A study of Homo sapiens with 11 samples.

How the data were processed

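KYSE30 esophageal squamous carcinoma cells were sequenced by RNA-seq 24 h after treatment with IMMU132 at 6 µg/ml, a TROP2 antibody carrying the topoisomerase I inhibitor SN-38, with the complex I inhibitor IACS010759 at 6 µM, with both, or with neither. There were 3 control libraries, 2 with IMMU132, 3 with IACS010759 and 3 with the combination, 11 in total, all human cells of 1 line.

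The deposited file holds FPKM values for 58735 genes in each of the 11 libraries. HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and the build hg38 are named per the submitters' processing notes, without their roles, and neither the filters nor the counting strand are given. Identifiers and coordinates of all 58735 genes matched GENCODE release 29. Multiplied by gene length, 100% of the deposited FPKM values in every library were whole multiples of 1 step, within a tolerance of 0.01, so the reads behind each value could be read back. Libraries held 13957398 to 17250175 reads in genes, which makes 1 read in a gene of 1 kb 0.0546 to 0.0714 FPKM. The divisor in the file equals a median-ratio size factor times the mean library, so the deposited FPKM values are already scaled between these 11 libraries, and the planned rescaling by median ratios changed little. Reads from overlapping genes, antisense pairs or close paralogs are uncertain.

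Values were taken as log2(FPKM + 1), and the 13012 genes with a mean FPKM of at least 1 were tested, 10505 of them protein-coding. Adding 1 makes fold changes of weakly expressed genes too small. A linear model with 1 mean per group was fitted to all 11 libraries with limma 3.58.1 in R 4.3.3, using empirical Bayes with a trend and robust variances (7 residual degrees of freedom). The 6 contrasts were each treatment against control, the combination against each single drug, and the interaction. P-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. A count by non-overlap has a chance share of 10% for 3 against 3 libraries, where 52.7% to 64.8% of genes had no overlap between groups, and of 20% for the 2 comparisons with the 2 IMMU132 libraries, where 63.2% and 60.3% had none. Of 39 gene lists, 36 had at least 3 measured members and were tested with fry, and with camera at a preset correlation of 0.01 and at an estimated correlation. Gene span was compared as the median log2 fold change of protein-coding genes of at least 100 kb minus that of genes under 10 kb, with an exact permutation of libraries.

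Genes named are, for each contrast, the 10 largest rises and falls among protein-coding genes with no overlap between the groups (5 and 5 for the interaction, without the overlap condition), up to 4 members of each described list by adjusted p, and TACSTD2, TOP1, CDKN1A, MT-ND1, DDIT4, PIK3CA, AKT1, MTOR and PTEN. No block was used, because the replicate numbers are not said to mark a shared culture or day. The residuals gave no sign of pairing either. Those of 15 pairs with the same number correlated at −0.06 to 0.06, and 2 of 11 libraries were closest to their own number.

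The alternatives chosen before the data were examined were a pseudocount of 0.1, no filter, a filter at a mean FPKM of 5, scaling to the same total, quantile normalization, only the groups of the contrast, array weights, a replicate block, plain empirical Bayes, and leaving out each library. Limma-voom on the recovered reads, genes of at least 200 bases, protein-coding genes only, and list tests under other scalings, filters and left-out libraries were added after. DESeq2 and edgeR were not run, and limma-voom was the only fit on the recovered reads. The steps were tested on simulated data in which 200 genes were changed, with 12691 to 12713 genes in each fit. At 1.5-fold, 77% of 100 changed genes were recovered for IMMU132 against control, 78% for IACS010759 against control, 83% for the combination against control and 71% for the interaction; at 2-fold, 85%, 87%, 89% and 80%. With no gene changed, 0 to 3 genes were called per contrast. The simulated reads had 1 dispersion of 0.00136 for all genes, the median over well-covered genes in control. These numbers hold for that setting and do not give the power or error rate in the real libraries.

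Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 for reading the file and drawing figures.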

Results

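TACSTD2, the gene for the cell surface protein TROP2 that IMMU132 binds, rose in KYSE30 esophageal squamous carcinoma cells 24 h after every treatment. Its mean was 199 ± 4.3 FPKM (SD) in control libraries (n = 3), 446 ± 19 with IMMU132 (n = 2), 299 ± 20 with the complex I inhibitor IACS010759 (n = 3) and 514 ± 18 with both (n = 3). The log2 fold changes against control were 1.16 ± 0.06 (SE), 0.58 ± 0.05 and 1.36 ± 0.05 (limma adjusted p = 2.3e-07, 2.7e-05 and 1.4e-08). Between the combination and IMMU132 alone the change was 0.20 ± 0.06 (adjusted p = 0.016), a call that ended without IMMU132 replicate 1 (0.16, adjusted p = 0.13). The gene gained less from IMMU132 when IACS010759 was present (interaction −0.38 ± 0.07, adjusted p = 0.0059). TOP1, which encodes the enzyme that the SN-38 payload of IMMU132 traps on DNA, stood at 43.5, 41.3, 40.3 and 42.9 FPKM in the 4 groups, with adjusted p = 0.38, 0.15 (0.044 with a replicate block) and 0.76 against control. CDKN1A, a cell cycle inhibitor induced by p53, rose from 43.3 to 129 FPKM with IMMU132 (1.54 ± 0.16) and to 97.1 with the combination (1.15 ± 0.15), and fell to 27.5 with IACS010759 (−0.63 ± 0.15).

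The 4 groups separated along the first 2 principal components, which held 45.2% and 20.7% of the variance. Correlations of log2 values were 0.982 to 0.985 within groups and 0.935 to 0.970 between groups. P-values measure only the spread between these libraries, since the labels do not say whether the replicates were separate cultures. IMMU132 had 2 libraries, so its spread was in large part borrowed from the other groups in the fit. Gene lists were fixed before the data were examined. For them, fry tests whether the members move on balance in one direction, without comparing them with other genes. Each fry result below is followed by the adjusted p of camera with an estimated correlation between members, which does make that comparison. Camera at the preset correlation of 0.01, below the estimate for most lists, makes it too. There 54 of the 60 list results named kept direction and outcome, and 1, described below, turned around. Calls were lost there for PI3K-AKT-mTOR genes with IMMU132 (adjusted p = 0.18) and the combination (0.33), and mitochondrial genome genes with IMMU132 (0.065). With the combination, pro-apoptotic (0.29) and anti-apoptotic genes (0.13) lost theirs. Counts adjusted over the list alone are given where they differ from counts adjusted over all genes.

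IMMU132 raised genes of the squamous surface layers and lowered lipid synthesis genes. The 10 largest rises against control were SPRR2A (cornified envelope; 2.71 ± 0.19), AQP3 (water and glycerol channel; 2.46 ± 0.05, from 12.1 to 71.3 FPKM), ALPP (2.36 ± 0.05), GDF15 (stress cytokine; 2.36 ± 0.20, from 11.7 to 64.7 FPKM), APOBEC3B (cytidine deaminase; 2.28 ± 0.09), KRT9 (2.25 ± 0.11), KRT13 (suprabasal keratin; 2.25 ± 0.12), IL1RN (2.22 ± 0.12), HR (2.12 ± 0.07) and S100P (2.11 ± 0.18). The 10 largest falls were SCD (fatty acid desaturase; −2.19 ± 0.07, from 347 to 75.4 FPKM), FAF1 (−1.95 ± 0.05), ADK (−1.93 ± 0.10), DPYD (−1.93 ± 0.07), FASN (fatty acid synthase; −1.71 ± 0.05, from 334 to 101 FPKM), SND1 (−1.71 ± 0.04), PTPRK (−1.63 ± 0.06), GPHN (−1.57 ± 0.11), HMGA2 (−1.56 ± 0.05) and ACACA (acetyl-CoA carboxylase; −1.55 ± 0.05). Limma called 5737 of 13012 genes at an adjusted p under 0.05, 2478 higher and 3259 lower. By at least 2-fold, 205 were higher and 122 lower (142 and 100 of them protein-coding). With every library scaled to the same total the calls numbered 3561 higher and 2135 lower, so the balance of the 2 directions depended on the scaling.

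**Figure D1:**
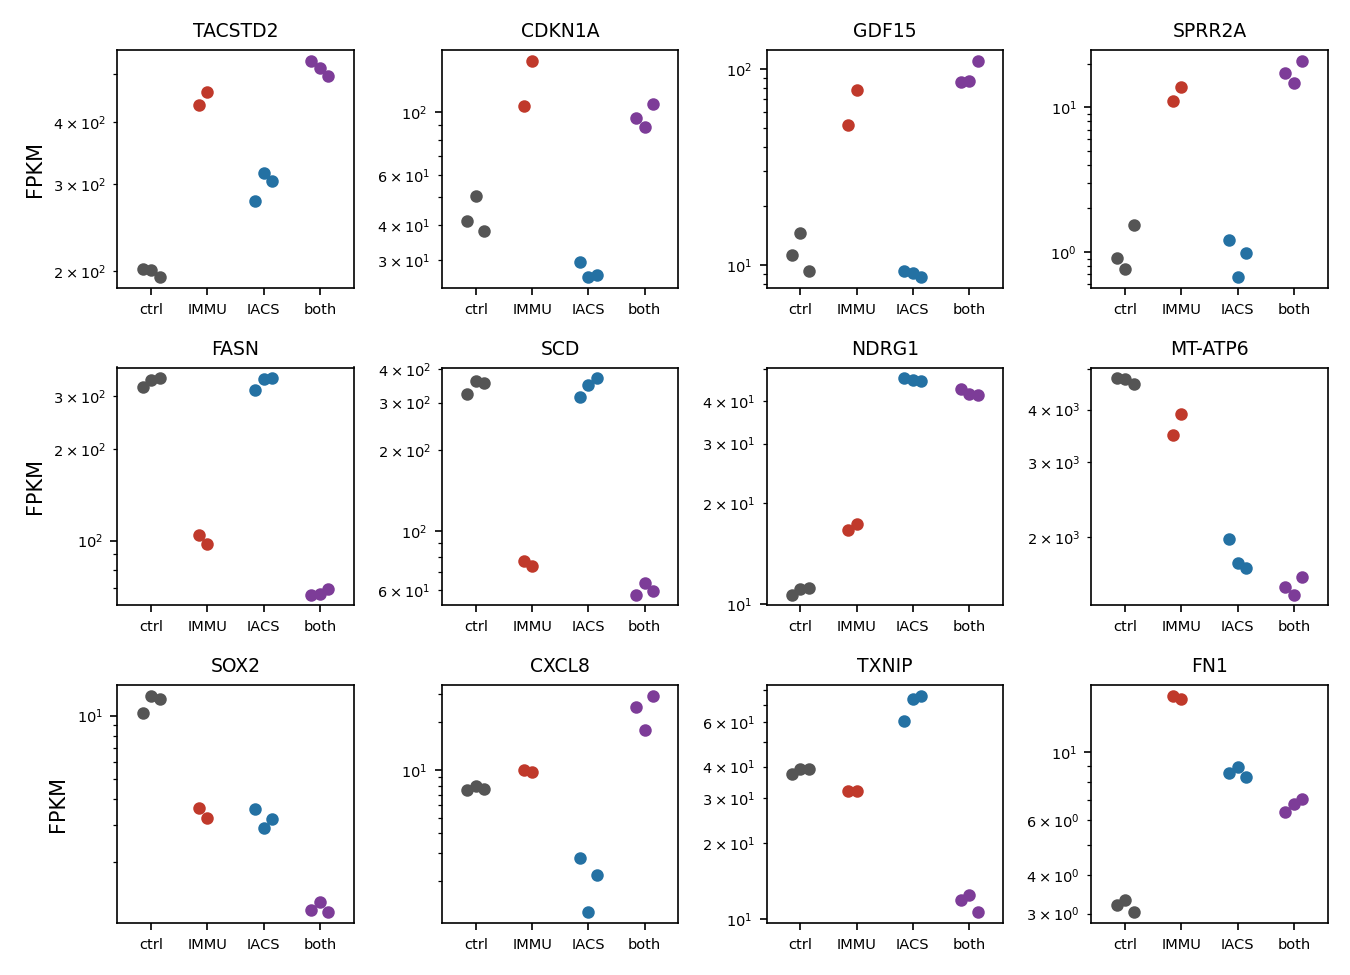
FPKM of 12 genes in each of the 11 libraries, on a logarithmic axis (ctrl, control; IMMU, IMMU132; IACS, IACS010759; both, the combination).

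Squamous terminal differentiation genes moved up with IMMU132. Of 21 measured members, 17 rose, 0 fell and 4 did not pass, with a median of 0.80 (fry adjusted p = 4.1e-07; adjusted p = 0.056 with an estimated correlation). The proteases KLK6 (1.47 ± 0.04) and KLK5 (1.52 ± 0.07), which shed cornified cells, the keratin KRT16 (1.32 ± 0.06) and the envelope protein PPL (0.75 ± 0.04) were among them. Of 27 p53 targets, 21 rose and 2 fell (3 fell adjusted over the list alone), led by DDB2 (DNA damage recognition; 1.10 ± 0.09), BTG2 (1.15 ± 0.11), FDXR (0.70 ± 0.07) and PLK3 (0.75 ± 0.08), with a median of 0.37 (fry adjusted p = 0.00015; adjusted p = 0.25 with an estimated correlation). Of 23 pro-apoptotic genes, 9 rose and 0 fell (7 and 0 over the list alone), among them BCL2L11 (BIM; 0.73 ± 0.07), CASP3 (0.45 ± 0.06), the TRAIL receptor TNFRSF10A (0.43 ± 0.07) and BMF (0.64 ± 0.11). Fry gave the list adjusted p = 1e-04 (adjusted p = 0.20 with an estimated correlation). Interferon-stimulated genes rose in 17 of 31 and fell in 6, with the DNA sensor adaptor TMEM173 (STING) at 1.22 ± 0.05, OAS1 at 1.21 ± 0.06, SAMD9 at 1.13 ± 0.06 and OAS3 at 1.24 ± 0.08 (fry adjusted p = 2.4e-05; adjusted p = 0.27 with an estimated correlation).

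Genes of the sterol and fatty acid pathways fell with IMMU132. Cholesterol biosynthesis genes fell in 21 of 25 and rose in 0, with DHCR7 (the last step of the pathway; −0.96 ± 0.03), the transcription factor SREBF2 (−0.96 ± 0.04), the lipoprotein receptor LDLR (−0.75 ± 0.04) and LSS (−0.73 ± 0.05); the median was −0.56 (fry adjusted p = 2.7e-06; adjusted p = 0.20 with an estimated correlation). Fatty acid synthesis genes fell in 10 of 14 and rose in 1, with SREBF1, the lipogenic transcription factor, at −1.09 ± 0.05 beside FASN, ACACA and SCD (fry adjusted p = 9e-07; adjusted p = 0.25 with an estimated correlation). Glycolysis genes fell in 17 of 25 and rose in 4, including ENO1 (−0.82 ± 0.04), LDHA (−0.62 ± 0.03), GAPDH (−0.59 ± 0.04) and PFKP (−0.48 ± 0.04). The fry adjusted p was 1.6e-06 (adjusted p = 0.20 with an estimated correlation). NRF2 targets fell in 15 of 23 (16 over the list alone) and rose in 2, with TKT (−0.92 ± 0.04), TXNRD1 (−0.76 ± 0.03), ME1 (−1.10 ± 0.07) and the ferritin chain FTL (−0.61 ± 0.05). Their fry adjusted p was 4.9e-07 (adjusted p = 0.081 with an estimated correlation). G1/S and DNA replication genes fell in 27 of 50 (28 over the list alone) and rose in 6. The helicase subunits MCM5 (−0.82 ± 0.05) and MCM6 (−0.73 ± 0.06) and GINS1 (−0.67 ± 0.05) fell while E2F2 rose (1.03 ± 0.07). In fry this list had adjusted p = 7.7e-05 (adjusted p = 0.33 with an estimated correlation).

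The kinases and adaptors of the PI3K-AKT-mTOR pathway gave a mixed picture with IMMU132. Of 35 measured, 3 rose, 12 fell and 20 did not pass. The mTORC2 subunit MAPKAP1 fell by 1.08 ± 0.04 on the log2 scale, the receptors EGFR by 1.00 ± 0.05 and IGF1R by 0.77 ± 0.04, and the mTORC1 subunit RPTOR by 0.99 ± 0.07. As deposited the list's median was −0.05 and fry pointed downward (adjusted p = 1.4e-05; adjusted p = 0.49 with an estimated correlation). With every library scaled to the same total the median was 0.06, while fry still pointed downward (adjusted p = 0.0448). PIK3CA fell (−0.32 ± 0.06) and PTEN, which opposes the pathway, fell as well (−0.35 ± 0.06). AKT1 was at −0.19 ± 0.07 (adjusted p = 0.047; 0.41 with every library scaled to the same total), a call that also ended (adjusted p = 0.053 to 0.17) without any 1 of the control or IMMU132 replicates, IACS010759 replicates 2 and 3 or combination replicate 1. MTOR was at −0.05 ± 0.04 (adjusted p = 0.32). DDIT4, an inhibitor of mTORC1, fell from 151 to 81.4 FPKM (−0.89 ± 0.06). Among 27 negative regulators 7 rose and 9 fell, with INPP4B at −0.89 ± 0.07, EIF4EBP2 at 0.41 ± 0.05 and FLCN at 0.42 ± 0.07. That list had a median of 0.02 but a mean of −0.06 and a fry result downward (adjusted p = 0.0055), which turned upward with every library scaled to the same total (adjusted p = 0.157) and with an estimated correlation (adjusted p = 0.91). Its call ended without IMMU132 replicate 1 (adjusted p = 0.104).

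Long genes fell with IMMU132, the longest most. Protein-coding genes that span at least 100 kb of the genome (n = 1814) had a median change of −0.27, against 0.02 for genes under 10 kb (n = 2041), a difference of −0.293. Among the long genes 1046 fell and 139 rose (1079 and 146 over the list alone). As a list they reached a fry adjusted p of 9e-07 (adjusted p = 0.056 with an estimated correlation). Of the 10 largest falls 8 are long genes: FAF1 (523 kb), ADK (558 kb), DPYD (917 kb), SND1 (440 kb), PTPRK (552 kb), GPHN (674 kb), HMGA2 (142 kb) and ACACA (322 kb). The 1051 genes with the longest spans, of 10 equal bins (median 211 kb), had a median change of −0.38. With the combination the difference between long and short genes was −0.458, 1242 long genes fell and 166 rose (1273 and 171 over the list alone), and the bin of longest genes stood at −0.53. Fry on the long genes gave adjusted p = 8.6e-08 with the combination (adjusted p = 0.060 with an estimated correlation). With limits of 200 kb and 20 kb the difference was −0.53 for IMMU132 and −0.81 for the combination. With IACS010759 the difference was 0.093 (0.0223 on residuals after a fit on gene length, less than the SD of 0.056 between control libraries) and the bin of longest genes stood at 0.02. Between the combination and IMMU132 alone it was −0.173, with medians of −0.12 for long and 0.05 for short genes. There 604 long genes fell and 170 rose (627 and 179 over the list alone). For the interaction the difference was −0.278, with medians of −0.13 and 0.14. The gap between long and short genes was thus wider with both drugs than with IMMU132 alone. Per library the difference was −0.29 ± 0.01 (SD) with IMMU132, −0.46 ± 0.05 with the combination, 0.09 ± 0.01 with IACS010759 and 0.00 ± 0.06 in control. The exact permutation p was 0.1 for each of these comparisons with control, the smallest possible for IMMU132 with 10 splits and the smallest possible for a 2-sided test of 3 against 3. Camptothecins, the class of SN-38, are known to stall RNA polymerase along long genes.

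**Figure D2:**
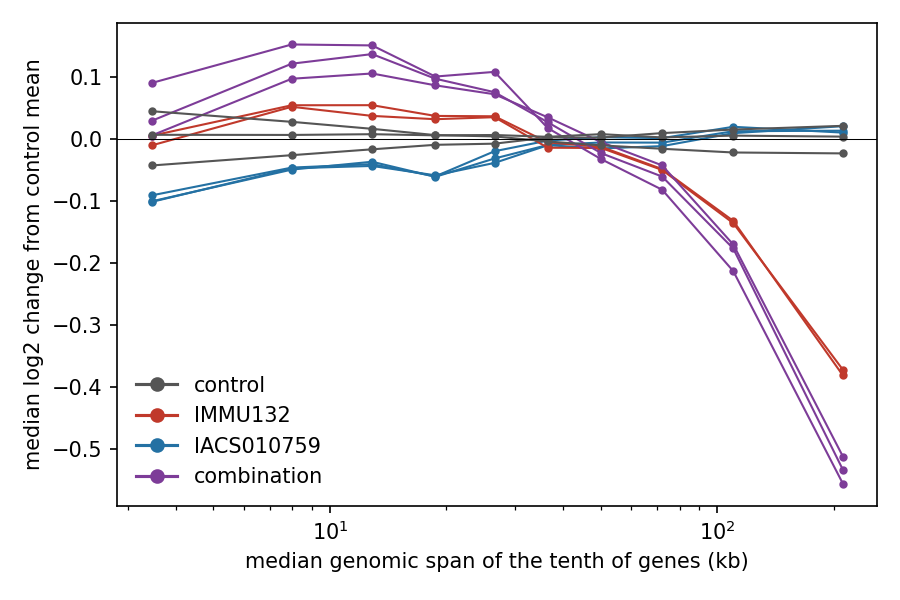
Median log2 change from the control mean for 10 equal bins of protein-coding genes ordered by genomic span, 1 line per library.

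IACS010759 raised genes of the hypoxia and glycolysis programs and lowered part of the mitochondrial transcripts. The 10 largest rises were NDRG1 (hypoxia-inducible; 1.98 ± 0.03, to 46.4 FPKM), the histone genes HIST2H2BE (1.59 ± 0.13), HIST1H2BC (1.49 ± 0.12) and HIST1H2AC (1.41 ± 0.08), GPRC5A (1.39 ± 0.04), IGFBP3 (1.38 ± 0.04), the collagen cross-linking LOXL2 (1.37 ± 0.05), the clock gene PER1 (1.25 ± 0.09), HIST1H2BD (1.24 ± 0.10) and BNIP3 (mitophagy receptor; from 10.4 ± 0.56 to 25.1 ± 0.20 FPKM). The 10 largest falls were MT-ATP8 (−1.63 ± 0.13), the squamous lineage factor SOX2 (−1.57 ± 0.08, from 11.6 to 3.24 FPKM), the chemokine CXCL8 (−1.52 ± 0.20), MT-ND3 (−1.40 ± 0.15), MT-ATP6 (−1.38 ± 0.06), ARL14 (−1.38 ± 0.23), RGS2 (−1.30 ± 0.10), NCOA5 (−1.27 ± 0.13), FAM111B (−1.26 ± 0.10) and CHAC2 (−1.22 ± 0.13). Limma called 5245 genes, 2388 higher and 2857 lower (2650 and 2363 with every library scaled to the same total). By at least 2-fold, 107 were higher and 49 lower, but only 24 and 18 of these were protein-coding.

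The 13 protein genes of the mitochondrial genome did not move alike with IACS010759: 8 fell, 2 rose and 3 did not pass. The ATP synthase subunit MT-ATP6 dropped from 4681 to 1799 FPKM, MT-CO3 from 6134 to 3060, and the complex I subunits MT-ND1 (−0.92 ± 0.09), MT-ND2 (−0.90 ± 0.08) and MT-ND5 (−0.37 ± 0.03) fell too. MT-CO1 rose by 0.39 ± 0.04 and MT-CYB by 0.36 ± 0.06, and MT-CO2 (−0.02) and MT-ND4 (0.07) did not pass as deposited; these 4 were chosen after their values were seen. With every library scaled to the same total MT-ND4 passed (0.11, adjusted p = 0.014), and quantile normalization, which pins the most abundant transcripts by construction, left MT-CO1 at 0.00. The list fell on balance (median −0.37, fry adjusted p = 0.00026; adjusted p = 0.50 with an estimated correlation). With IMMU132 alone 7 of the 13 fell and 0 rose, with MT-CO3 (−0.47 ± 0.08), MT-CO1 (−0.24 ± 0.05), MT-ATP6 (−0.34 ± 0.07) and MT-ND2 (−0.39 ± 0.09; call lost without IMMU132 replicate 1, −0.28, adjusted p = 0.059). Quantile normalization also ended the last 3 of these calls. The list with IMMU132 had a median of −0.17 (fry adjusted p = 0.019; adjusted p = 0.62 with an estimated correlation), and did not pass without control replicate 1 (adjusted p = 0.0591), without IMMU132 replicate 1 (adjusted p = 0.123), with quantile normalization (adjusted p = 0.0584) or with every library scaled to the same total (adjusted p = 0.129). The share of reads in mitochondrial rRNA, examined after the results were seen, went the other way with IACS010759 and the combination. It was 0.765% to 0.789% in control, 0.919% to 1.02% with IACS010759, 1.10% to 1.17% with the combination, and 0.846% and 0.872% with IMMU132. It is a share of all reads in genes, which is not the scale of the deposited values. The divisor in the file was 0.979 to 0.995 times those reads in control and 1.06 to 1.08 times with IMMU132. The share therefore cannot be set against the falls with IMMU132. For all genes of the mitochondrial genome, rRNA included, the share was 5.43% to 5.90% in control and 5.52% to 5.60% with IACS010759. It was 4.91% to 4.96% with the combination, and 5.15% and 5.60% with IMMU132. This total, also examined after the results were seen, stayed within the control range with IACS010759, although the median of the 13 genes fell. Reads of MT-ATP6 and MT-ATP8, which overlap, and of genes with near-identical nuclear copies are uncertain. Of 36 nuclear complex I genes, 5 rose and 11 fell (14 over the list alone), with NDUFV2 at 0.94 ± 0.11, NDUFB9 at −0.44 ± 0.05, NDUFB1 at −0.62 ± 0.08 and NDUFA5 at −0.32 ± 0.06; the fry adjusted p was 0.088, and 0.0435 with every library scaled to the same total, 0.0342 with a replicate block and 0.00682 without control replicate 3 (adjusted p = 0.64 with an estimated correlation). Mitochondrial ribosomal protein genes fell in 39 of 77 and rose in 1 (42 and 2 over the list alone), led by MRPS18C (−0.68 ± 0.07), MRPL47 (−0.59 ± 0.07), MRPL12 (−0.42 ± 0.05) and MRPL14 (−0.41 ± 0.05). By fry the adjusted p came to 0.00038 (adjusted p = 0.24 with an estimated correlation).

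**Figure D3:**
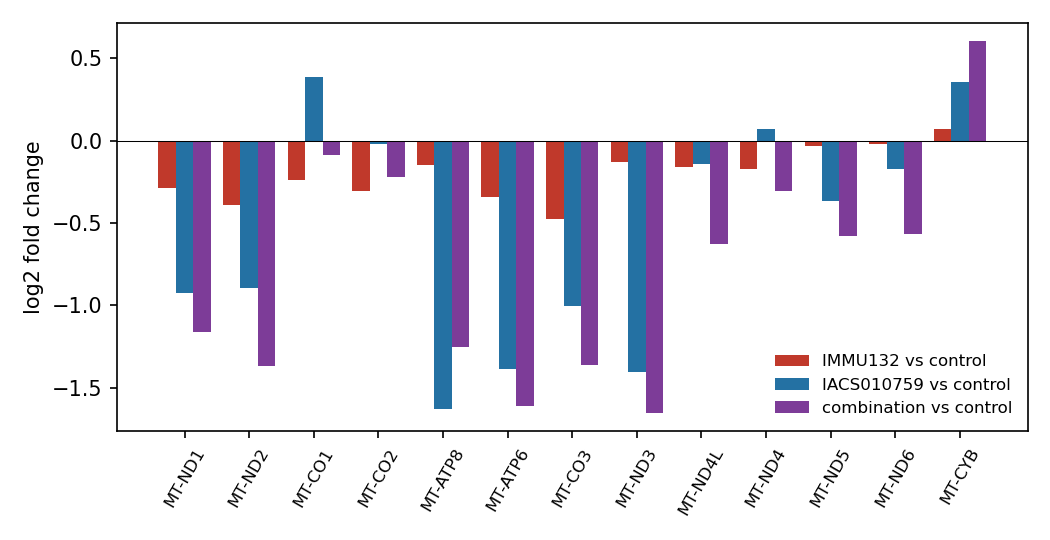
Log2 fold changes against control of the 13 protein genes of the mitochondrial genome, in genome order, with IMMU132, IACS010759 and the combination.

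Hypoxia-inducible genes rose with IACS010759 in 13 of 18 and fell in 1 (14 and 1 over the list alone). Beside NDRG1 and BNIP3 these included the mitophagy receptor BNIP3L (0.90 ± 0.05) and the collagen prolyl hydroxylase P4HA1 (0.95 ± 0.06); the median was 0.36 (fry adjusted p = 5e-07; adjusted p = 0.15 with an estimated correlation). Glycolysis genes rose in 17 of 25 and fell in 2 (18 and 2 over the list alone), with LDHA (0.48 ± 0.03), PGK1 (0.54 ± 0.04), the glucose transporter SLC2A1 (0.35 ± 0.03) and GAPDH (0.35 ± 0.03). Fry gave the list adjusted p = 6e-06 (adjusted p = 0.15 with an estimated correlation). LDHA and GAPDH thus moved up with IACS010759 and down with IMMU132. NRF2 targets also went up here, 12 of 23 higher and 3 lower, with TXNRD1 (0.65 ± 0.03), the glutathione synthesis gene GCLC (0.69 ± 0.04), FTL (0.49 ± 0.04) and NQO1 (0.40 ± 0.04). The fry adjusted p was 6e-06 (adjusted p = 0.15 with an estimated correlation). Replication-dependent histone genes rose in 15 of 29 and fell in 0 (16 and 0 over the list alone; fry adjusted p = 0.00017; adjusted p = 0.24 with an estimated correlation). Histone genes share sequence with each other, which leaves the level of each single one uncertain. Most of these transcripts lack a poly(A) tail, so RNA selection may bear on the rise; this was not tested.

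Nucleolar, DNA replication and mitosis genes fell on balance with IACS010759. Nucleolar and RNA polymerase I genes fell in 21 of 25 and rose in 0 (23 and 0 over the list alone), with the polymerase I factor UBTF (−0.66 ± 0.03), PES1 (−0.44 ± 0.03), NCL (−0.47 ± 0.04) and MYBBP1A (−0.48 ± 0.04). Their fry adjusted p was 2.4e-05 (adjusted p = 0.22 with an estimated correlation). G1/S genes fell in 36 of 50 and rose in 0 (36 and 1 over the list alone), including UHRF1 (−0.64 ± 0.05), the polymerase subunit POLD1 (−0.41 ± 0.04), FEN1 (−0.70 ± 0.07) and MCM7 (−0.36 ± 0.04). In fry this list had adjusted p = 2e-05 (adjusted p = 0.15 with an estimated correlation). G2/M genes fell in 27 of 49 and rose in 0 (28 and 1 over the list alone), with the mitotic transcription factor FOXM1 (−0.52 ± 0.04), KIF20B (−0.64 ± 0.05), CDC25A (−0.68 ± 0.06) and BIRC5 (−0.32 ± 0.03). As a list they reached a fry adjusted p of 0.00015 (adjusted p = 0.24 with an estimated correlation). Heat shock genes fell in 9 of 15 and rose in 2, with the chaperones HSPD1 (−0.40 ± 0.03), HSPA8 (−0.82 ± 0.07), HSPH1 (−0.76 ± 0.07) and HSP90AA1 (−0.34 ± 0.03). By fry the adjusted p came to 0.00014 (adjusted p = 0.36 with an estimated correlation). Interferon-stimulated genes fell in 14 of 31 and rose in 5 (14 and 6 over the list alone), with OASL (−0.54 ± 0.04), SAMD9 (−0.74 ± 0.05), the RNA sensor DDX58 (−0.51 ± 0.05) and IFIT3 (−0.54 ± 0.06). Fry on the whole list gave adjusted p = 0.00014 (adjusted p = 0.30 with an estimated correlation). PI3K-AKT-mTOR genes split, 8 higher and 10 lower of 35 (9 and 10 over the list alone), with EIF4B at 0.46 ± 0.03, the insulin receptor substrate IRS2 at 0.89 ± 0.07, EIF4G1 at −0.31 ± 0.03 and MAPKAP1 at −0.27 ± 0.04 (fry adjusted p = 0.62; adjusted p = 0.93 with an estimated correlation). DDIT4 rose from 151 to 217 FPKM (0.52 ± 0.05), and MTOR (−0.18 ± 0.03) and PTEN (−0.20 ± 0.05) fell. The PTEN call ended without control replicate 1 (adjusted p = 0.061).

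Markers of other cell types were nearly absent from these cells. None of the blood and immune markers reached the level for testing, and of the fibroblast and endothelial markers COL1A1 and CDH5 did. With IMMU132, CDH5 rose from 0.49 to 3.82 FPKM (1.70 ± 0.11) and COL1A1 from 1.70 to 3.43 FPKM (0.71 ± 0.07). With IACS010759 the changes were −0.33 for CDH5 and 0.18 for COL1A1, and neither call held: for COL1A1 it ended without any 1 of the 11 libraries (adjusted p = 0.0508 to 0.145), and for CDH5 without control replicate 1 or 3 or any IACS010759 replicate (adjusted p = 0.0508 to 0.0949).

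The changes under the single drugs overlapped in part. Of the genes that limma called, 694 were higher with both IMMU132 and IACS010759 where their numbers alone would give 455, and 1006 were lower with both where 716 would be expected. In opposite directions, 484 were higher with IMMU132 and lower with IACS010759 (544 expected) and 531 the reverse (598 expected). The correlation of the log2 fold changes over 13012 genes was 0.173 and their covariance 0.0240. Both comparisons use the same 3 control libraries, so part of the excess may come from them: in 100 simulations with no gene changed the covariance averaged 0.0114 (0.00997 to 0.0139) and the correlation 0.448, and 0 genes were called in both. Since no gene was changed there, that 0 does not tell how many shared calls the controls add in these data. The covariance above the simulated mean was 0.0126.

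The combination lowered lipid synthesis and raised differentiation genes, as IMMU132 did, and raised hypoxia genes and lowered part of the protein genes of the mitochondrial genome, as IACS010759 did; some of the latter fell with IMMU132 alone too. The 10 largest rises against control were SPRR2A (3.18 ± 0.17), SPRR2E (3.01 ± 0.20), GDF15 (2.91 ± 0.18, from 11.7 to 94.1 FPKM), AQP3 (2.76 ± 0.04), the immediate early receptor NR4A1 (2.70 ± 0.08, from 1.24 to 13.6 FPKM), S100P (2.59 ± 0.16), APOBEC3B (2.40 ± 0.08), HAPLN3 (2.26 ± 0.13), TM4SF1 (2.09 ± 0.06) and AL121753.1 (2.01 ± 0.25). The 10 largest falls were SOX2 (−2.50 ± 0.08, from 11.6 to 1.21 FPKM), SCD (−2.50 ± 0.06), ADK (−2.37 ± 0.09), FASN (−2.29 ± 0.05, from 334 to 67.5 FPKM), the matrix protein TNC (−2.26 ± 0.06), DPYD (−2.25 ± 0.06), FAF1 (−2.22 ± 0.05), UTRN (−2.09 ± 0.06), SPOCK1 (−2.07 ± 0.08) and ACACA (−1.99 ± 0.04). Limma called 7847 genes, 3810 higher and 4037 lower (4697 and 3192 with every library scaled to the same total). By at least 2-fold, 321 were higher and 378 lower (193 and 299 of them protein-coding).

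Lipid synthesis genes fell with the combination. Cholesterol genes fell in 23 of 25 and rose in 1, with DHCR7 (−1.32 ± 0.03), LDLR (−0.91 ± 0.04), LSS (−1.02 ± 0.04) and DHCR24 (−1.61 ± 0.07), median −0.66 (fry adjusted p = 3e-07; adjusted p = 0.19 with an estimated correlation). Fatty acid synthesis genes fell in 10 of 14 and rose in 1, with SREBF1 at −1.35 ± 0.04 beside FASN, ACACA and SCD (median −0.69, fry adjusted p = 8.6e-08; adjusted p = 0.23 with an estimated correlation). Against IMMU132 alone 10 of the 14 fatty acid genes fell and 1 rose (11 and 1 over the list alone), with FASN (−0.58 ± 0.05), ACACA (−0.44 ± 0.05), ME1 (−0.50 ± 0.07) and ACSL3 (−0.35 ± 0.05). Tested together they had a fry adjusted p of 0.0003 (adjusted p = 0.33 with an estimated correlation). Of the 25 cholesterol genes, 8 fell against IMMU132 alone, 2 rose and 15 did not pass (10 and 3 over the list alone), median −0.15. With IACS010759 alone against control, 10 of the 25 cholesterol genes rose and 2 fell (11 and 2 over the list alone), median 0.15. The interaction subtracts this rise from the change against IMMU132. The interaction was negative for both lists: 13 cholesterol genes lay below the sum of the 2 drugs and 0 above (15 and 0 over the list alone), including HMGCS1 (−0.91 ± 0.10), DHCR24 (−0.96 ± 0.11), DHCR7 (−0.37 ± 0.05) and FDFT1 (−0.71 ± 0.10), and 9 fatty acid genes below and 0 above (11 and 1 over the list alone), including ACSS2 (−1.21 ± 0.10), FASN (−0.57 ± 0.07), ELOVL6 (−0.72 ± 0.15) and ACACA (−0.30 ± 0.07). The fry adjusted p was 0.0011 for each of them (adjusted p = 0.24 with an estimated correlation).

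Hypoxia-inducible genes rose with the combination in 13 of 18 and fell in 2 (14 and 2 over the list alone), with NDRG1 (1.86 ± 0.03), BNIP3 (1.37 ± 0.06), the histone demethylase KDM3A (1.25 ± 0.06) and BNIP3L (0.67 ± 0.05). Their fry adjusted p was 9.1e-08 (adjusted p = 0.19 with an estimated correlation). Of the 13 mitochondrial genome genes 11 fell and 1 rose, with MT-ATP6 (−1.61 ± 0.06), MT-ND5 (−0.58 ± 0.03), MT-CO3 (−1.36 ± 0.07), MT-ND2 (−1.36 ± 0.08) and MT-ND1 (−1.16 ± 0.09). In fry this list had adjusted p = 7.5e-06 (adjusted p = 0.39 with an estimated correlation). Nuclear complex I genes fell in 21 of 36 and rose in 6, with NDUFV2 up from 0.98 to 3.58 FPKM, NDUFB3 at −1.07 ± 0.10, NDUFS6 at −1.07 ± 0.11 and NDUFB1 at −0.66 ± 0.08 (fry adjusted p = 0.0089; adjusted p = 0.58 with an estimated correlation). Autophagy and lysosome genes rose in 17 of 33 and fell in 6, with the lipid transfer protein ATG2A (0.96 ± 0.05), GLA (0.71 ± 0.05), BECN1 (0.64 ± 0.05) and GABARAPL1 (0.60 ± 0.05). As a list they reached a fry adjusted p of 9.1e-08 (adjusted p = 0.19 with an estimated correlation).

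Both pro-apoptotic and anti-apoptotic genes rose on balance with the combination. Pro-apoptotic genes rose in 10 of 23 and fell in 6, with the BH3-only genes BCL2L11 (1.04 ± 0.06) and BMF (1.24 ± 0.10) and HTRA2 (0.82 ± 0.10) up and CYCS down (−0.61 ± 0.04). By fry the adjusted p came to 0.00015 (adjusted p = 0.42 with an estimated correlation); among genes with a mean FPKM of at least 5 the list did not pass (adjusted p = 0.305). Anti-apoptotic genes rose in 5 of 9 and fell in 1, with BIRC3 (0.38 ± 0.05), BCL2L1 (0.32 ± 0.04), CFLAR (0.42 ± 0.06) and BCL2L2 (0.52 ± 0.08). Fry gave the list adjusted p = 2.1e-06 (adjusted p = 0.38 with an estimated correlation). Of 27 p53 targets, 17 rose and 3 fell (18 and 3 over the list alone), with PLK3 (1.09 ± 0.08), FDXR (0.91 ± 0.06), TP53 itself (0.61 ± 0.04) and PLK2 (−0.62 ± 0.04). The fry adjusted p was 0.00023 (adjusted p = 0.41 with an estimated correlation). Squamous differentiation genes rose in 15 of 21 and fell in 4 (15 and 5 over the list alone), with KLK6 (1.06 ± 0.04), KRT16 (0.98 ± 0.05) and PPL (0.53 ± 0.03) beside SPRR2A. Their fry adjusted p was 6e-07 (adjusted p = 0.22 with an estimated correlation). PI3K-AKT-mTOR genes fell in 16 of 35 and rose in 7, with MAPKAP1 (−1.56 ± 0.04), IGF1R (−1.27 ± 0.04), RPTOR (−1.56 ± 0.06) and EGFR (−1.16 ± 0.05). In fry this list had adjusted p = 2.3e-06 (adjusted p = 0.58 with an estimated correlation). MTOR fell by 0.41 ± 0.03 on the log2 scale, PTEN by 0.46 ± 0.05 and DDIT4 by 0.49 ± 0.05, PIK3CA was at 0.01 ± 0.05, and AKT1 fell by 0.22 ± 0.06 (−0.13, adjusted p = 0.10, with every library scaled to the same total).

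The cell cycle genes parted in the combination: replication genes fell on balance, and of the mitosis genes more rose than fell. G1/S genes fell in 37 of 50 and rose in 5 (38 and 5 over the list alone), with GINS1 (−1.37 ± 0.04), MCM6 (−1.11 ± 0.05), MCM3 (−0.72 ± 0.03) and MCM5 (−0.98 ± 0.05). As a list they reached a fry adjusted p of 3e-07 (adjusted p = 0.19 with an estimated correlation). G2/M genes rose in 26 of 49 and fell in 11 (27 and 12 over the list alone), with KIF2C (0.65 ± 0.04) and INCENP (0.55 ± 0.04) up and KIF4A (−0.87 ± 0.05) and AURKA (−0.48 ± 0.03) down. By fry the adjusted p came to 0.0035 (adjusted p = 0.58 with an estimated correlation). The mitosis genes lay above the sum of the 2 drugs in 30 of 49 and below in 1 (34 and 2 over the list alone), with the kinases PLK1 (0.73 ± 0.07) and TTK (0.51 ± 0.05), ECT2 (0.57 ± 0.05) and INCENP (0.45 ± 0.05). Fry gave the list adjusted p = 0.00065 (adjusted p = 0.24 with an estimated correlation).

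**Figure D4:**
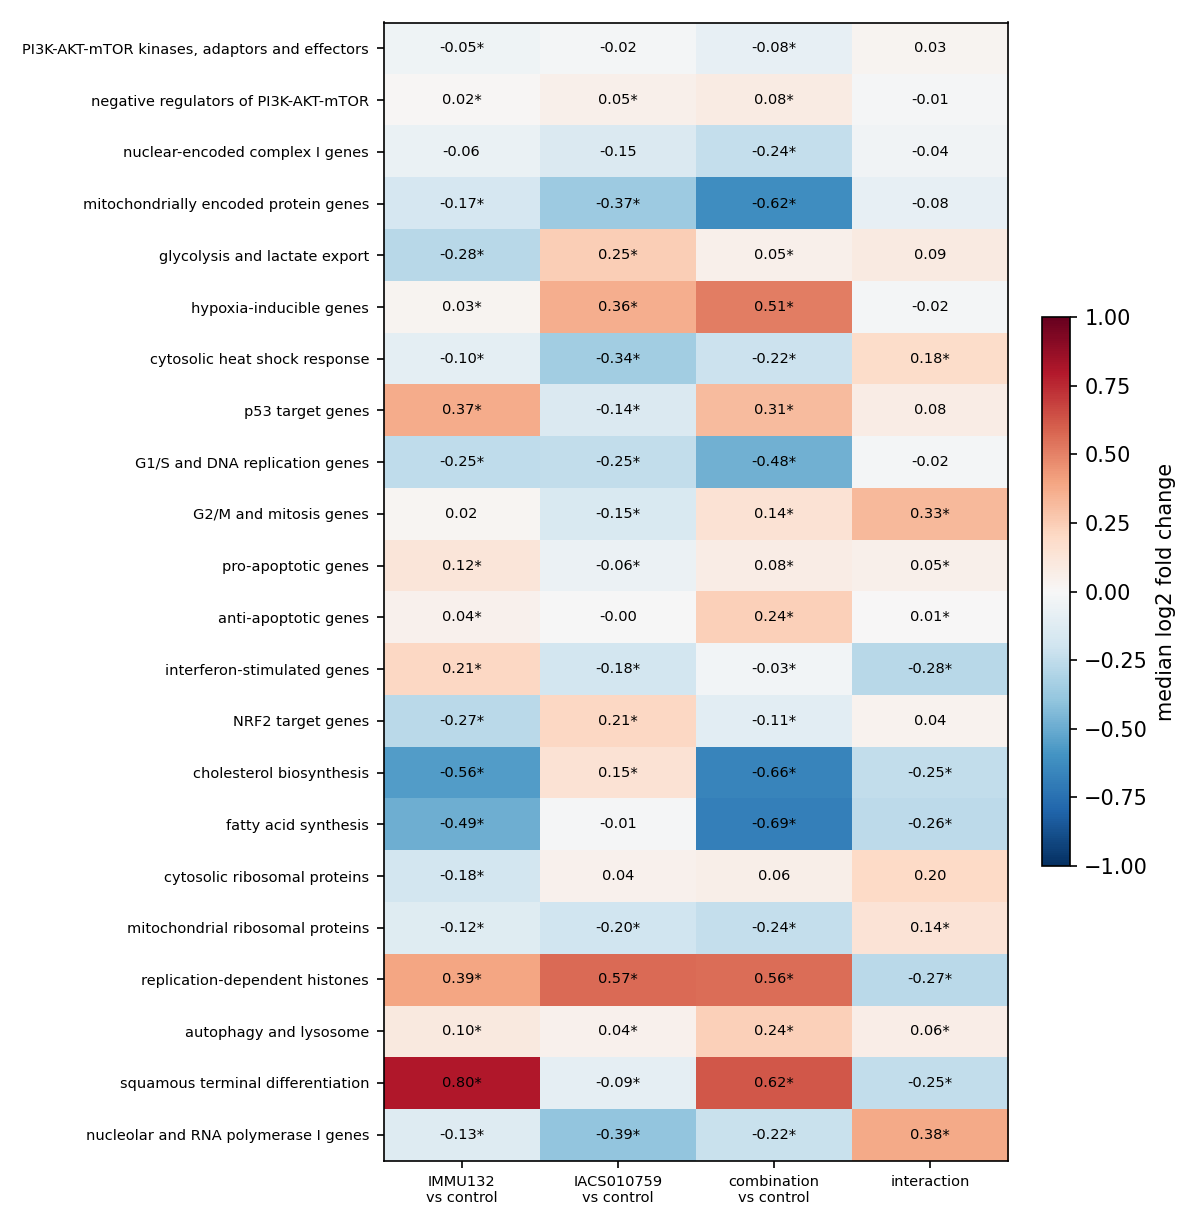
Median log2 fold change of the described gene lists against control and for the interaction, with an asterisk where the fry adjusted p was under 0.05. Medians that changed sign under the same total per library or quantile normalization: with IMMU132, PI3K-AKT-mTOR kinases, heat shock and complex I; with IACS010759, PI3K-AKT-mTOR kinases, anti-apoptotic and fatty acid genes; with the combination, interferon-stimulated genes; for the interaction, PI3K-AKT-mTOR kinases, their negative regulators, anti-apoptotic genes and NRF2 targets.

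Compared with IMMU132 alone, the combination raised hypoxia genes and lowered interferon-stimulated genes and protein genes of the mitochondrial genome. The 10 largest rises were NDRG1 (1.28 ± 0.04), DDX47 (1.27 ± 0.11), NR4A1 (1.24 ± 0.09), BNIP3 (1.23 ± 0.07), AMN1 (1.23 ± 0.09), CCNL1 (1.23 ± 0.06), HIST1H2BH (1.19 ± 0.15), CXCL8 (1.17 ± 0.23), SPRR2E (1.15 ± 0.23) and KDM3A (1.12 ± 0.06). The SPRR2E call ended with 0.1 added before the logarithm (1.31, adjusted p = 0.21). The 10 largest falls were the envelope precursor SPRR1B (−1.58 ± 0.10, from 81.4 to 26.5 FPKM), MT-ND3 (−1.52 ± 0.17), TXNIP (glucose uptake brake; −1.39 ± 0.09), ANKRD2 (−1.32 ± 0.12), FGD3 (−1.29 ± 0.10), SPRR3 (−1.28 ± 0.08), MT-ATP6 (−1.27 ± 0.07), BMP4 (−1.22 ± 0.11), SNAI2 (−1.21 ± 0.12) and CLIC3 (−1.15 ± 0.11). Limma called 4840 genes, 2536 higher and 2304 lower (2277 and 2362 with every library scaled to the same total, 2304 and 2475 with quantile normalization), and 3148 without IMMU132 replicate 1 or 3212 without IMMU132 replicate 2. By at least 2-fold, 75 were higher and 68 lower, of which 19 and 29 were protein-coding.

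In that comparison hypoxia genes rose in 12 of 18 and fell in 0 (13 and 0 over the list alone), with NDRG1, BNIP3, KDM3A and BNIP3L (0.81 ± 0.05). The fry adjusted p was 1.8e-06 (adjusted p = 0.12 with an estimated correlation). Glycolysis genes rose in 15 of 25 and fell in 1, with GAPDH (0.55 ± 0.04), HK2 (0.50 ± 0.04), SLC2A1 (0.40 ± 0.04) and ENO2 (0.93 ± 0.09). Their fry adjusted p was 9e-06 (adjusted p = 0.12 with an estimated correlation). Against control, 10 of the 25 rose and 10 fell with the combination (11 and 10 over the list alone). NRF2 targets rose in 13 of 23 and fell in 2, with TXNRD1 (0.53 ± 0.03), GCLC (0.68 ± 0.04), FTL (0.53 ± 0.05) and FTH1 (0.54 ± 0.05). In fry this list had adjusted p = 8.5e-06 (adjusted p = 0.12 with an estimated correlation). Against control, 7 of the 23 rose and 12 fell with the combination. Cytosolic ribosomal protein genes rose in 49 of 79 and fell in 1, with RPL3 (0.65 ± 0.04), RPS3A (0.46 ± 0.04), RPL10A (0.43 ± 0.04) and RPL10 (0.49 ± 0.05). As a list they reached a fry adjusted p of 0.0065 (adjusted p = 0.60 with an estimated correlation). Against control, 39 of these 79 genes fell and 1 rose with IMMU132 alone (43 and 1 over the list alone). With the combination against control 24 rose and 9 fell (22 and 8 over the list alone). Mitochondrial genome genes fell in 10 of 13 and rose in 2, with MT-ND5 (−0.55 ± 0.03), MT-ND2 (−0.98 ± 0.09) and MT-CO3 (−0.89 ± 0.08). By fry the adjusted p came to 0.00022 (adjusted p = 0.39 with an estimated correlation). Interferon-stimulated genes fell in 23 of 31 and rose in 1, with OASL (−0.71 ± 0.04), IFI44 (−0.73 ± 0.05), ISG15 (−0.63 ± 0.05) and TMEM173 (−0.67 ± 0.05). Fry on the whole list gave adjusted p = 6.3e-06 (adjusted p = 0.12 with an estimated correlation). Squamous differentiation genes fell in 14 of 21 and rose in 3 (14 and 4 over the list alone), with KRT17 (−0.86 ± 0.06) and KLK5 (−0.85 ± 0.07) beside SPRR1B and SPRR3. Tested together they had a fry adjusted p of 1.8e-05 (adjusted p = 0.12 with an estimated correlation).

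Compared with IACS010759 alone, the combination lowered cholesterol and fatty acid genes and raised p53 target and squamous differentiation genes. The 10 largest rises were SPRR2A (3.25 ± 0.17), GDF15 (3.23 ± 0.18), SPRR2E (3.10 ± 0.20), CXCL8 (3.02 ± 0.20), AQP3 (2.98 ± 0.04), S100P (2.50 ± 0.16), NR4A1 (2.32 ± 0.08), the activin antagonist FST (2.14 ± 0.11), KRT13 (2.07 ± 0.11) and APOBEC3B (2.03 ± 0.08). The 10 largest falls were SCD (−2.49 ± 0.06), TXNIP (−2.48 ± 0.08), LPP (−2.29 ± 0.06), FASN (−2.28 ± 0.05), SPOCK1 (−2.25 ± 0.08), ADK (−2.25 ± 0.09), FAF1 (−2.19 ± 0.05), FGFBP1 (−2.10 ± 0.04), TBC1D5 (−2.03 ± 0.07) and EXOC6B (−2.01 ± 0.06). Limma called 7492 genes, 3803 higher and 3689 lower (4443 and 3106 with every library scaled to the same total), with 242 and 351 by at least 2-fold (158 and 260 of them protein-coding). Cholesterol genes fell in 22 of 25 and rose in 1 (22 and 2 over the list alone), with SREBF2 at −1.02 ± 0.04, DHCR7 at −1.33 ± 0.03, LDLR down from 93.5 to 46.3 FPKM and DHCR24 at −1.65 ± 0.07 (fry adjusted p = 1.2e-07; adjusted p = 0.14 with an estimated correlation). Fatty acid genes fell in 12 of 14 and rose in 0, with ME1 at −1.53 ± 0.06 and ACACA at −1.85 ± 0.04 (fry adjusted p = 6.1e-08; adjusted p = 0.16 with an estimated correlation). All 27 p53 targets passed, 23 higher and 4 lower, with FDXR (1.05 ± 0.06), PLK3 (1.05 ± 0.08), DDB2 (1.06 ± 0.08) and PLK2 (−0.74 ± 0.04). Their fry adjusted p was 3.4e-05 (adjusted p = 0.29 with an estimated correlation). G2/M genes rose in 40 of 49 and fell in 4 (40 and 5 over the list alone), with INCENP (0.65 ± 0.04), ECT2 (0.59 ± 0.04), KIF2C (0.64 ± 0.04) and KIF23 (0.67 ± 0.04). In fry this list had adjusted p = 5.3e-06 (adjusted p = 0.24 with an estimated correlation). Pro-apoptotic genes rose in 13 of 23 and fell in 3, with CASP3 (0.75 ± 0.05), BCL2L11 (0.82 ± 0.06) and BAX (0.50 ± 0.06) up and BID down (−0.46 ± 0.05). As a list they reached a fry adjusted p of 3.6e-06 (adjusted p = 0.16 with an estimated correlation). Squamous differentiation genes rose in 16 of 21 and fell in 3 (16 and 4 over the list alone), with KLK6 (1.06 ± 0.04) and KRT80 (0.73 ± 0.04). By fry the adjusted p came to 2.2e-07 (adjusted p = 0.14 with an estimated correlation).

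The interaction asks whether the combination departs from the sum of the single drugs on the log2 scale. CXCL8, a neutrophil chemokine, stood furthest above it (2.69 ± 0.30): 7.67 FPKM in control, 9.93 with IMMU132, 2.10 with IACS010759 and 24.1 with both. The kinase SGK1 (1.40 ± 0.09), FST (1.37 ± 0.16), SPRR2E (1.23 ± 0.31) and the glutathione-degrading stress gene CHAC1 (1.15 ± 0.17) followed. The SPRR2E call ended without IMMU132 replicate 1 (1.04, adjusted p = 0.078), with 0.1 added before the logarithm (1.82, adjusted p = 0.23), with no filter (adjusted p = 0.0608) and with limma-voom (2.18, adjusted p = 0.0605). Furthest below the sum were the matrix protein FN1 (−2.25 ± 0.07), TXNIP (−2.22 ± 0.12, from 70.1 FPKM with IACS010759 to 11.7 with both), HIST1H2BC (−1.79 ± 0.18), IGFBP3 (−1.72 ± 0.06) and FGD3 (−1.70 ± 0.14). Nucleolar genes lay above the sum in 18 of 25 and below in 0 (22 and 0 over the list alone), with PES1 (0.67 ± 0.04), UBTF (0.58 ± 0.05), DDX21 (0.63 ± 0.08) and NPM1 (0.49 ± 0.07). Fry gave the list adjusted p = 0.00065 (adjusted p = 0.24 with an estimated correlation). Interferon-stimulated genes lay below in 14 of 31 and above in 1, with TMEM173 (−0.65 ± 0.07), DDX60 (−0.57 ± 0.09), IFI44 (−0.39 ± 0.07) and OAS3 (−0.57 ± 0.10). The fry adjusted p was 0.00097 (adjusted p = 0.24 with an estimated correlation). PI3K-AKT-mTOR genes lay above in 5 of 35 and below in 8 (6 and 9 over the list alone), with IGF1R (−0.45 ± 0.06), RRAGA (0.52 ± 0.08), PIK3R3 (−0.62 ± 0.12) and EGFR (−0.35 ± 0.07), a list result that did not pass (fry adjusted p = 0.21; adjusted p = 0.86 with an estimated correlation). Limma called 3243 genes, 1895 above the sum and 1348 below (1359 and 1462 with every library scaled to the same total), and 2044 without IMMU132 replicate 1. By at least 2-fold, 33 lay above and 79 below, of which 11 and 34 were protein-coding.

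Part of the change under each drug recurred in the presence of the other, in comparisons that share no library. IACS010759 against control and the combination against IMMU132 correlated at 0.404 over 13012 genes, with 1056 genes higher in both (465 expected from the numbers alone) and 1057 lower in both (506 expected). IMMU132 against control and the combination against IACS010759 correlated at 0.662, with 1794 higher in both (724 expected) and 2316 lower in both (924 expected). Opposite calls were below expectation in each case, at 181 and 255 genes for IACS010759 (423 and 557 expected) and 107 and 187 for IMMU132 (703 and 953 expected).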

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

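The tests of explanations below were chosen after the results were seen. A set of 10 genes changed with IMMU132 by a different amount with and without IACS010759, by a test of the difference itself (the interaction on the log2 scale). These were CXCL8 (2.69), SGK1 (1.40), FST (1.37), SPRR2E (1.23) and CHAC1 (1.15) above the sum of the single drugs, and FN1 (−2.25), TXNIP (−2.22), HIST1H2BC (−1.79), IGFBP3 (−1.72) and FGD3 (−1.70) below it. FN1 stood at 3.18 FPKM in control, 8.59 with IACS010759 and 6.73 with the combination, and rose with IMMU132 alone by 1.93 on the log2 scale. SPRR2E was at 0.433 FPKM in control, and its call ended without IMMU132 replicate 1 (1.04, adjusted p = 0.078) and in 3 other fits.

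Long genes were lower in the libraries that received IMMU132. A bias with gene length was set against this: on residuals after a linear fit on gene length the difference between long and short genes was −0.212 with IMMU132 and −0.358 with the combination, against −0.293 and −0.458 without it. These are far from 0 against an SD between libraries of at most 0.056, so length is not the whole cause. Within 4 equal bins of gene length the difference was −0.483 to −0.239 and −0.590 to −0.281. The ends of these ranges rest on few genes. The bin of greatest gene length held 14 genes spanning under 10 kb, and that of least held 73 spanning at least 100 kb. The middle bins gave −0.374 and −0.294 for IMMU132, and −0.565 and −0.500 for the combination. The slope per doubling of span went from −0.0613 to −0.0748 with length in the same model for IMMU132, and from −0.0892 to −0.117 for the combination. Low expression with the value added before the logarithm was argued against by the difference within 4 equal bins of mean expression, which was −0.203 or lower in every bin for both comparisons. The payload slowing transcription along the gene predicts that, among genes of at least 100 kb, the change falls further with span. Spearman's rho over the 1814 such genes was −0.424 or lower in each of the 5 libraries given IMMU132 and between −0.04 and 0.05 in the 6 others, which fits slowed transcription as a hypothesis, found and tested on the same data; RNA stability was not tested and stays open.

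The mitochondrial genome transcripts changed unevenly with IACS010759. A uniform loss of mitochondrial RNA is argued against by MT-CO1, the highest of the 13 genes, at 0.39 while MT-ATP6 stood at −1.38. Gene length is argued against as the whole cause by MT-ATP6 and MT-CO2, of 681 and 684 bases, whose changes differed by −1.36 ± 0.10 (SE); over the 13 genes length and change had a Spearman's rho of 0.577, shorter genes lower, so a part played by length stays open. Reads moved to nuclear copies of MT-ATP6 and MT-ND2 are argued against by the copies MTATP6P1 and MTND2P28, which fell too, by log2 fold changes of −1.79 and −0.98; other genes with copies were not tested. Over the 13 genes, the changes with IACS010759 against control and with the combination against IMMU132, which share no library, ranked alike (Spearman's rho 0.951), so the pattern went with IACS010759, and whether synthesis or decay of these RNAs differs stays open.

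Splits of the 6 libraries into 3 against 3 number 10 for each comparison, the real one included, too few for a share under 0.05. For IACS010759 against control the real split gave 5245 genes and the highest other split 1. For the combination against control these were 7847 and 0, and for the combination against IACS010759 they were 7492 and 0. In each comparison 1 split, the real one, gave as many genes. Every other split mixes libraries of both groups, so the difference between the groups enters the spread and few calls can arise. The low numbers of the other splits therefore decide nothing about chance.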

How the results depend on the processing

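The limma-voom fit, the limits to genes of at least 200 bases or to protein-coding genes, and the list tests under other scalings, filters and left-out libraries were chosen after seeing the data. The number of genes called stayed within 1.5 times its value in all 6 contrasts under a pseudocount of 0.1, a mean FPKM of at least 5, the same total per library, quantile normalization, array weights, the replicate block, plain empirical Bayes, limma-voom and both limits on genes, and in the 5 contrasts of 2 groups with only those groups in the fit. With no filter the interaction dropped to 2039 genes, where more weakly expressed genes entered the adjustment; the cause was not tested. Leaving out 1 library at a time gave 4138 to 5724 genes for IMMU132 against control, 4104 to 5284 for IACS010759 against control, 7232 to 7814 for the combination against control, 3148 to 4837 for the combination against IMMU132, 6859 to 7481 for the combination against IACS010759 and 2044 to 3012 for the interaction. The lowest for the combination against IMMU132 came without IMMU132 replicate 1 (3148; 3212 without replicate 2), and the lowest for the interaction without IMMU132 replicate 1 (2044). Those fits leave 1 IMMU132 library, assumed to vary like the other groups. With the replicate block the counts were 5461, 5090, 7764, 4474, 7402 and 2979, in the order of this paragraph, so a pairing by replicate number, for which the residuals gave no sign, would change little.

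The difference between long and short genes kept its direction throughout. With limits of 200 kb and 20 kb it was −0.53 for IMMU132 and −0.81 for the combination, and on residuals after a fit on gene length −0.212, 0.0223 for IACS010759, and −0.358; the cause was not tested. Without each library in turn it was −0.322 to −0.273 for IMMU132, 0.0651 to 0.116 for IACS010759 and −0.479 to −0.429 for the combination.

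Of the lists, the negative regulators of PI3K-AKT-mTOR with IMMU132 turned upward with camera (adjusted p = 0.905 at the preset and 0.908 at the estimated correlation) and with the same total per library (adjusted p = 0.157); the cause was not tested. None of the 60 list results named passed with the estimated correlation. At the preset correlation, besides the negative regulators, 5 lost their call and 54 kept direction and outcome. Of the 381 gene changes named no called one turned around, while some uncalled ones near 0, such as TOP1 and MTOR with IMMU132, changed sign with the same total per library (0.04 and 0.06). Calls were lost for 10 with no filter, 7 with quantile normalization, 6 with the same total per library, 6 with only the groups of the contrast, 5 with the replicate block, 4 with plain empirical Bayes, 3 with limma-voom, 2 each with array weights and a pseudocount of 0.1, and 1 with genes of at least 200 bases. Over the 11 fits that leave out 1 library the losses came to 68, a gene change being counted again in each fit that lost it. COL1A1 with IACS010759 was lost in all 11. Rescaling by median ratios gave 5247 genes for IACS010759 against control, 3244 for the interaction and unchanged numbers in the rest, since the deposited values already carry it. Depth of 13957398 reads or more leaves genes under 1 FPKM on few reads; those were tested only in the fit with no filter.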

Other observations

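The test in this part was chosen after the results were seen. The fall of PI3K-AKT-mTOR genes with IMMU132 may be shared with long genes as such. The 10 measured members of at least 100 kb had a median change of −0.41 (5 fell, 0 rose) and the 25 shorter members a median of 0.00 (7 fell, 3 rose). Of 100 random sets of genes with the same spans, 68 had a median at or below the −0.05 of the list, so the list's median did not stand out from genes of its spans. With the combination the medians were −0.79 and 0.01, and 67 of 100 sets were at or below the list's −0.08. The random sets were compared by median only. The list's mean with IMMU132 was −0.15, below its median, so the sets do not tell whether span accounts for the downward fry result.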
